A study of Mus musculus with 15 samples.

How the data were processed

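The deposited files hold 1 count per gene for each of 6 RNA libraries, and their values are whole numbers that were not normalised, per the file headers and the values. Per the labels' protocols, the authors extracted total RNA, removed ribosomal RNA with magnetic beads and prepared libraries. The submitters' processing notes name STAR 2.5.3a, featureCounts 2.0.0, limma and the build mm10, with no role or order. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Reads of overlapping, antisense or near-identical genes, such as immunoglobulin segments, can therefore be shared between them. Among the 9 chromatin immunoprecipitation and input samples, no values were analysed here.

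Groups and replicate numbers were taken from the sample titles, since the genotype tags say the opposite of the titles and descriptions for every RNA library. The files list 55335 gene identifiers, of which 54587 matched a symbol in a table of gene names and 748 did not. Of the tested genes, 241 had no symbol, and 16 of these were among the calls. Positions and gene types came from the RefSeq annotation of GRCm38.p6, which is mm10, by symbol. They were found for 11616 tested genes (88.8%), 10296 of them protein-coding. Whole gene spans are given, since counts were made per gene.

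Total counts ranged from 14092278 to 20803227 per library, and between 8.55% and 11% of them fell on the 10 genes with the most reads. Genes were kept by edgeR's filterByExpr function, which left 13077. Libraries were scaled by TMM and compared with edgeR 4.0.16 (quasi-likelihood test, no covariate) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The biological coefficient of variation was 0.109. CPM values use the TMM-scaled library sizes, and values are given as mean ± SD over 3 libraries unless marked SE. The SE of a log2 fold change was obtained from the fold change and the test's F statistic. No pair of libraries agreed within sampling noise (chi-square over degrees of freedom from 7.3 to 33.7). The sources used here name no molecular identifiers, so intervals and floors (3 counts) cover counting error only.

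Before the data were examined, 36 gene lists were fixed, of which 34 had at least 3 tested members. Lists and chromosomes were tested with camera from limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry (directional and mixed). Adjusted p of lists are over the 34 lists, and those of chromosomes over the 20 chromosomes. The genes named were also fixed by rule: Msl2, Blnk, Xist and the tested MSL members, the 6 protein-coding genes with the largest change in each direction among called genes with a mean log2 CPM of at least 2 and full separation of the groups, the 3 with the smallest p in each direction, and up to 2 called members per direction of each list. Immunoglobulin segments were reported only as lists. Genes named outside this rule are said to be so where they appear, and values of 1 called gene are not reported here.

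The scripts were tested on counts simulated from the real means, dispersions and library sizes, with 200 genes changed in a knockout against wild-type comparison of 3 and 3 libraries. Of 12782 genes tested there, 55.4% of 65 changed 1.5-fold were recovered, 73.8% of 65 changed 2-fold and 95.3% of 64 changed 4-fold. Besides these, 16 of 12558 unchanged genes were called, which is a share of the unchanged genes and not of the calls. A simulated list of 30 genes shifted by 0.4 on the log2 scale was called, and 0 of 20 unshifted lists were. Genes were simulated independently of each other, whereas estimated correlations in the real lists reached 0.787 for sterol synthesis. The simulation therefore does not check the preset correlation for lists of correlated genes. Alternatives were RLE scaling, library totals only, no filter on low counts, a filter at a mean log2 CPM of 2, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library. Leaving out both libraries numbered 2 was added after the data were seen.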

Results

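RNA was measured in cultured mouse pre-B cells that, per the labels, lack SLP65 (the adaptor protein encoded by Blnk, which relays signals from the pre-B cell receptor). Per the labels, the parental cells came from bone marrow, were grown from 1 single cell in medium with interleukin 7, and were edited with a guide RNA against Msl2 to give a knockout line. MSL2 is a ubiquitin ligase of the MSL complex, in which the acetyltransferase KAT8 (MOF) acetylates lysine 16 of histone H4. The comparison asked which genes differ in RNA level between the Msl2 knockout line and the wt clone. There were 3 libraries titled wild type and 3 titled knockout. Total counts were 14092278, 17437198 and 15784586 in the wild-type libraries and 16110623, 20803227 and 15250975 in the knockout libraries. At these depths a gene with 0 reads in 1 library is limited to between 0.144 and 0.213 CPM (reads scaled to a common library size), for counting error only. The 9 chromatin immunoprecipitation and input samples were not analysed here.

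The titles and the genotype tags of the labels contradicted each other in all 6 RNA libraries, and the groups follow the titles. Throughout, wild type and knockout mean the libraries so titled, and every direction depends on those titles. Msl2 (ENSMUSG00000066415.4, chromosome 9, 101074054 to 101104800, mm10) did not settle the question, because its RNA was not lost in either group. It was at 97.2, 99.3 and 92.3 CPM in wild-type replicates 1, 2 and 3 and at 105, 103 and 121 CPM in knockout replicates 1, 2 and 3. The means were 96.3 ± 3.6 and 110 ± 9.9 CPM (SD, n = 3 each), a log2 fold change of 0.19 ± 0.08 (SE) with an adjusted p of 0.302 in edgeR's quasi-likelihood test. The unadjusted p of that test was 0.0434, and all 3 knockout libraries lay above all 3 wild-type libraries. A count over the whole gene does not check a small edit in the coding sequence that leaves the transcript in place. Blnk (ENSMUSG00000061132.13), the gene of SLP65, was likewise transcribed in both groups, at 98.3 ± 19 and 112 ± 4.1 CPM (adjusted p 0.563), so these counts do not check the loss that the labels state. The other tested members of the MSL complex did not pass the test, and the list as a whole did not pass the camera set test (adjusted p 0.535). Kat8, its acetyltransferase, was at 29.6 ± 1.9 and 31.3 ± 0.98 CPM (adjusted p 0.768), Msl1 at 54.7 ± 6.1 and 56.9 ± 5.8 CPM (0.89) and Msl3 at 84.2 ± 4.2 and 83.1 ± 2.9 CPM (0.955). Within 500 kb of Msl2, 4 genes were tested (Stag1, Gm3081, Pccb and Ppp2r3a), and edgeR called 0 of them, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2. Their median log2 fold change was 0.10, with a range from -0.15 to 0.35, and the median ran from -0.023 to 0.219 without each library in turn.

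Of 13077 genes tested, 235 were higher and 365 lower in the knockout at an adjusted p under 0.05, and 103 and 186 of these differed at least 2-fold. Genes that rose most included Kynu, the kynureninase of tryptophan breakdown, Tlr7, an endosomal receptor for RNA, and Pla2g4a, the cytosolic phospholipase A2 that releases arachidonic acid. Genes that fell most included Tph1, the tryptophan hydroxylase of serotonin synthesis, and Erg, an ETS family transcription factor. In all 600 called genes the 3 knockout libraries lay on one side of the 3 wild-type libraries. Such separation held for 2735 tested genes, or 20.9%, against 10% by chance. The labels do not say whether replicates were separate cultures, and with 1 line per genotype the p-values measure the spread between these libraries, which may be technical. Without wild-type replicate 1 the counts were 138 higher and 242 lower, and without knockout replicate 1 the count of higher genes was 147. With both libraries numbered 2 left out, a choice made after the data were seen, 175 genes were higher and 224 lower. Without the low-count filter 482 of 26696 tested genes were higher and 721 lower, and with a filter at a mean log2 CPM of 2, 231 of 9635 were lower.

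Kynu (ENSMUSG00000026866.16, chromosome 2, 43555258 to 43683048) rose from 0.11 ± 0.2 to 15.1 ± 1.2 CPM, a log2 fold change of 6.81 ± 0.46 with an adjusted p of 6.71e-05. All 6 of its wild-type reads were in replicate 2, and without that library it was at least 152-fold higher, with a floor of 3 counts over the group. Tlr7 (X, 167303380 to 167330574) rose from 1.09 ± 1.3 to 20.5 ± 1.1 CPM (log2 4.13 ± 0.46) and Pla2g4a from 2.09 ± 2.4 to 27.6 ± 3.3 CPM (log2 3.63 ± 0.48). The log2 fold changes of Tlr7 and Pla2g4a were 5.87 and 5.32 without wild-type replicate 2. Akr1c13, an aldo-keto reductase with close paralogs that may share its reads, was 10.1-fold higher, Rgs7bp, which binds regulators of G protein signalling, was 6.6-fold higher, and Dtx1, a regulator of Notch signalling, was 6.33-fold higher. Lhfp had the smallest p among genes that rose, going from 10.8 ± 1.4 to 40.3 ± 4.2 CPM (adjusted p 6.71e-05).

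Erg (chromosome 16, 95359169 to 95586600) fell from 9.79 ± 1.3 to 0.78 ± 0.18 CPM, a log2 fold change of -3.62 ± 0.24 with an adjusted p of 6.71e-05. Fads6, of the fatty acid desaturase family, fell from 16.8 ± 4.9 to 0.57 ± 0.33 CPM and Adam33, a metalloprotease, from 8.21 ± 2.3 to 0.62 ± 0.22 CPM. Tph1 fell from 75.2 ± 11 to 5.64 ± 7.7 CPM (log2 -3.62 ± 0.62), with knockout replicates 1, 2 and 3 at 1.12, 14.6 and 1.25 CPM. Gcm2, a parathyroid transcription factor, fell from 10.2 ± 3.5 to 0.72 ± 0.68 CPM (log2 -3.71 ± 0.49). Without knockout replicate 2 the log2 fold changes were -5.97 for Tph1, -4.82 for Gcm2 and -5.41 for Fads6. Rnf125, a ubiquitin ligase, fell from 11.2 ± 1.7 to 0.47 ± 0.81 CPM (adjusted p 0.00514 in edgeR and 0.307 in DESeq2), and all 30 of its knockout reads were in replicate 2, without which it was at least 115-fold lower (same floor). Bcl2, an inhibitor of apoptosis, had the smallest p of all tested genes and fell 3.8-fold, from 37.3 ± 4.1 to 9.77 ± 1.2 CPM. Camkv, a kinase-like protein, fell 4.84-fold, from 45.9 ± 8.9 to 9.44 ± 0.65 CPM.

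**Figure D1:**
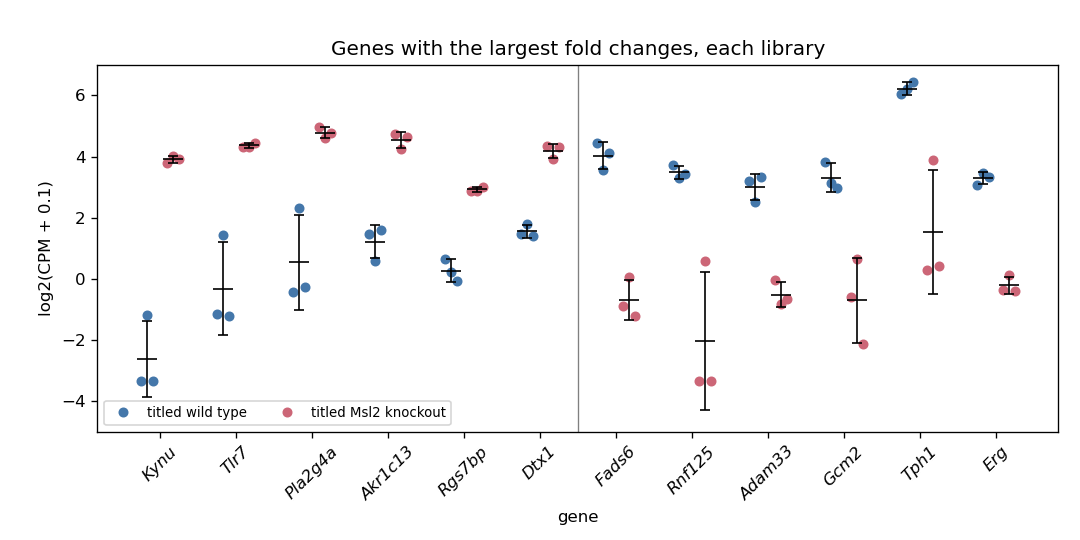
Expression of the 6 protein-coding genes with the largest positive (left) and the 6 with the largest negative (right) log2 fold changes, among called genes with a mean log2 CPM of at least 2 and full separation of the groups, as log2(CPM + 0.1) on the vertical axis, 1 point per library and 3 per group, with bars for the mean ± SD. In each gene the points of the groups do not overlap. Wild-type replicate 2 stands above the other wild-type libraries for Kynu, Tlr7 and Pla2g4a, and knockout replicate 2 above the other knockout libraries for Fads6, Tph1, Gcm2 and Rnf125.

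Of 20 tested genes in a list of interleukin 7 receptor signalling and STAT5 targets, 5 fell and 2 rose (6 and 3 adjusted over the list alone). The median log2 fold change was -0.12, or -0.19 without wild-type replicate 3. The camera set test, which compares a list with the other genes, gave an adjusted p of 0.0018 with its preset correlation between genes and an adjusted p of 0.433 with an estimated correlation. Il7r, the receptor chain itself, fell 2.9-fold from 82 ± 12 to 28.1 ± 11 CPM (adjusted p 0.00392), and Bcl2 fell as above. Bcl2l1, which encodes the anti-apoptotic BCL-XL, rose from 42.7 ± 2.4 to 68.6 ± 16 CPM, and Ccnd3, a cyclin of pre-B cell division, from 510 ± 13 to 641 ± 48 CPM. The Bcl2l1 call was lost without wild-type replicate 2 or 3 (adjusted p 0.0854 and 0.0574), and the Ccnd3 call without any 1 of the 6 libraries (adjusted p from 0.0642 to 0.171). Among 17 BCL2 family and caspase genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone). Bcl2a1b, whose reads may be shared with near-identical copies, was at 5.02 ± 0.29 and 8.68 ± 0.035 CPM, and Bid at 93.2 ± 4.5 and 74.1 ± 3.3 CPM. Bcl2a1b lost its call without wild-type replicate 1 (adjusted p 0.0587), and Bid without any 1 library (adjusted p from 0.0623 to 0.11). The list as a whole did not pass camera (adjusted p 0.535), and its median (0.04) and mean (-0.06) differed in sign.

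Among 23 tested transcription factors of the B lineage, 2 fell and 0 rose, with 3 and 4 adjusted over the list alone. These were Erg and Spib, an ETS factor of B cells, at 67.5 ± 2.9 in the wild type and 46.6 ± 7.5 CPM in the knockout. The list's median log2 fold change was 0.15 and its mean -0.06, which differ in sign (camera adjusted p 0.778). Without wild-type replicate 3 the median was 0.06 and the camera direction turned (adjusted p 0.818). Among 19 pre-B and B cell receptor components, 1 rose (3 adjusted over the list alone), the inhibitory receptor gene Cd22, at 63.4 ± 4.9 and 88.2 ± 6.4 CPM (camera adjusted p 0.26 for the list). Of 21 markers of later B cell stages, 2 rose and 2 fell, with 5 and 8 adjusted over the list alone (camera adjusted p 0.232). Cxcr5, the follicular homing receptor, fell 7.14-fold from 9.58 ± 1.7 to 1.27 ± 0.92 CPM, with a log2 fold change of -2.83 and of -3.62 without knockout replicate 2. H2-Aa, an MHC class II chain, was 2.08-fold lower, Fcrl1, an Fc receptor-like protein of B cells, 1.81-fold higher and Cxcr4, the receptor of CXCL12, 1.35-fold higher. Of 7 markers of earlier progenitors, 2 rose. Ly6a (Sca-1) rose 2.88-fold, with knockout libraries at 118, 46.4 and 51.7 CPM, and the cytokine receptor gene Flt3 rose 2.71-fold (camera adjusted p 0.1 for the list). Several of these calls were lost without 1 library. Spib lost its call without wild-type replicate 2 or 3 or knockout replicate 2 or 3 (adjusted p from 0.0566 to 0.0825), and H2-Aa without wild-type replicate 1 or 3 or knockout replicate 2 or 3 (from 0.0685 to 0.0802). Cxcr4 lost it without wild-type replicate 1 or 3 or any 1 knockout library (from 0.0509 to 0.113), and also with library totals only (0.0668) or a filter at a mean log2 CPM of 2 (0.0595). Flt3 lost it without wild-type replicate 1 or 3 or knockout replicate 1 (from 0.0648 to 0.0762), Ly6a without wild-type replicate 1 or 2 (0.0772 and 0.0617) and Cd22 without wild-type replicate 1 (0.0507). H2-Aa also missed the threshold in DESeq2 (adjusted p 0.0538). Of 15 genes of V(D)J recombination, edgeR called 0, with 3 at an unadjusted p under 0.05 and 0 in DESeq2 (camera adjusted p 0.313). The recombination gene Rag2, named outside the rule, had at most 1 read in each of wild-type replicates 1 and 3 but 27 in wild-type replicate 2. In knockout replicates 1 and 3 it had at least 20 reads each. Set tests of some lists passed when libraries were left out, but only with the preset correlation, as the adjusted p with an estimated correlation in the same fits ran from 0.326 to 0.922. These were the receptor components without wild-type replicate 2 (adjusted p 0.00155) or without both libraries numbered 2 (0.00227), V(D)J recombination without wild-type replicate 2 (0.0465), the later B cell markers without knockout replicate 1 (0.000245), and the progenitor markers without wild-type replicate 2 or knockout replicate 1 or 3 (0.0327, 0.0459 and 0.0325) or without both libraries numbered 2 (0.0159).

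Of 16 tested immunoglobulin kappa V segments, 3 rose and 0 fell (5 and 1 adjusted over the list alone), with a median log2 fold change of 0.60. All 4 tested lambda segments had positive values, with a median of 1.07, but edgeR called 0 of them, with 2 at an unadjusted p under 0.05, 2 adjusted over the list alone and 1 in DESeq2. The camera adjusted p was 0.0018 for the kappa and 0.0141 for the lambda list, and the adjusted p with an estimated correlation was 0.433 and 0.724. The lambda median was 1.86 without wild-type replicate 2 and 2.25 without both libraries numbered 2. Levels were low, with group medians of 1.2 and 1.69 CPM for kappa and 0.975 and 1.88 CPM for lambda. Reads of these segments can be shared between near-identical copies. The heavy chain V segments (4 tested) and the heavy chain constant regions (2 tested, too few for the set test) had 0 called genes (camera adjusted p 0.968 for the heavy chain V list), with 0 and 1 at an unadjusted p under 0.05 and 0 in DESeq2. The list of constant regions was drawn up to hold kappa as well, but no kappa constant gene was tested. Without the low-count filter the heavy chain V list passed camera (adjusted p 0.00948, and adjusted p 0.445 with an estimated correlation). Of its 39 segments then tested, 23 were at or under 3 reads in both groups, and with segments that had a group at 0 set to their bound (or to 0 where both groups were at or under the floor) the median was 0.

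Lists of growth and metabolism differed by small amounts. Cell cycle genes, replication-dependent histones, oxidative phosphorylation and sterol synthesis passed camera with its preset correlation, but each had an adjusted p of 0.887 with an estimated correlation. Of 40 S and G2/M phase genes, 35 had positive log2 fold changes (median 0.13, adjusted p 0.00414), and 2 rose and 1 fell. The kinetochore genes Cenpf and Cenpe were 1.25-fold and 1.23-fold higher and Mcm5, of the replicative helicase, 1.36-fold lower. Of 58 replication-dependent histone genes, 51 had positive values (median 0.09, adjusted p 0.00485) and edgeR called 0. Of 73 nuclear genes of oxidative phosphorylation, 63 had negative values (median -0.07, adjusted p 0.00485) and 1 fell, the ATP synthase gene Atp5a1, from 1693 ± 134 to 1249 ± 48 CPM. Of 23 sterol synthesis genes, 19 had negative values (median -0.12, adjusted p 0.0434) and edgeR called 0. Among 23 genes of the unfolded protein and integrated stress responses, 19 had negative values (median -0.13, adjusted p 0.0257, and adjusted p 0.706 with an estimated correlation). The called member was Psat1, an enzyme of serine synthesis, which fell from 277 ± 11 to 36.4 ± 32 CPM (log2 -2.90 ± 0.45). Knockout replicates 1, 2 and 3 were at 17.2, 72.9 and 18.9 CPM, and the log2 fold change was -3.93 without replicate 2.

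Several of these calls were lost when 1 library was left out, which also leaves fewer samples in the fit. The set test missed the threshold for the cell cycle list without wild-type replicate 1 or 2 or knockout replicate 3 (adjusted p 0.0801, 0.11 and 0.0535) and for the histone genes without the same libraries (0.762, 0.178 and 0.0923). It did so for oxidative phosphorylation without wild-type replicate 3 (0.59) or knockout replicate 2 (0.131), and for the stress responses without wild-type or knockout replicate 1 (0.0955 and 0.0566). The sterol list missed it without wild-type replicate 1 or 3 or knockout replicate 1 or 2 (0.282, 0.144, 0.685 and 0.251). With a filter at a mean log2 CPM of 2, the sterol and stress lists missed it too (0.0795 and 0.0841). The medians of these lists moved by over 1.5 times without some libraries, between 0.09 and 0.22 for the cell cycle, -0.03 and 0.35 for the histones, -0.11 and -0.01 for oxidative phosphorylation, and -0.33 and -0.03 for the sterol genes, while that of the stress responses was -0.08 without wild-type replicate 1. Cenpe and Cenpf lost their calls without any 1 library (adjusted p from 0.0671 to 0.149 and from 0.0601 to 0.131). Their log2 fold changes in those fits ran from 0.249 to 0.343 and from 0.262 to 0.357, so no single library set them. Mcm5 lost its call without wild-type replicate 1 or 3 or knockout replicate 1 or 2 (from 0.0635 to 0.135) and Atp5a1 without knockout replicate 2 (0.0772).

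Markers of other cell types were scarce. Of 22 T and NK cell markers in the files, 6 were tested, and 2 of these fell. Lck, a Src family kinase of lymphocytes, fell from 136 ± 2.8 to 83.2 ± 2.7 CPM (adjusted p 0.000468) and Lat, an adaptor of T cell receptor signalling, from 5.98 ± 1.8 to 1.85 ± 0.75 CPM. The list passed camera (median log2 fold change -0.42, adjusted p 0.00548) but not with an estimated correlation (adjusted p 0.567) or without wild-type replicate 2 (0.0637) or both libraries numbered 2 (0.153). Its median was -0.16 without knockout replicate 3 and -0.71 without knockout replicate 1. The Lat call was lost without wild-type replicate 1 (0.0619). Of 5 tested erythroid and megakaryocyte markers, 1 fell, the transcription factor gene Gata1, from 1.85 ± 0.31 to 0.24 ± 0.15 CPM (camera adjusted p 0.348 for the list). Of 4 myeloid and 3 stromal or endothelial markers tested, edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 (camera adjusted p 0.638 and 0.493). Of 9 tested imprinted genes, 2 fell (3 adjusted over the list alone, camera adjusted p 0.0814 for the list). Grb10, an adaptor of growth factor receptors, fell from 150 ± 35 to 43.9 ± 26 CPM and lost its call without knockout replicate 1 (adjusted p 0.0553). Igf2r had 34 reads in the wild type and 1 in the knockout, a ratio of 37.5 with a 95% exact counting interval from 6.29 to 1524. The imprinted list passed camera without wild-type replicate 3 or knockout replicate 2 (adjusted p 0.0323 and 0.0145, and adjusted p 0.531 and 0.617 with an estimated correlation).

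Of 21 FOXO target genes, 2 fell and 0 rose (3 and 3 adjusted over the list alone), namely Il7r and the transcriptional regulator gene Cited2, which was 1.52-fold lower. Of 15 NF-kappaB targets, 1 rose (Bcl2a1b) and 1 fell, the lymphotoxin gene Lta, from 108 ± 16 to 33.8 ± 10 CPM (adjusted p 0.000755). Of 17 interferon-stimulated genes, 1 fell, the guanylate-binding protein gene Gbp3, from 91.2 ± 10 to 56.5 ± 4.1 CPM. Of 81 ribosomal protein genes, 1 was lower, Rpl22l1 (adjusted p 0.049, and from 0.125 to 0.183 without wild-type replicate 1 or 3 or knockout replicate 2 or 3), and 0 adjusted over the list alone. The Rpl22l1 call was also lost with RLE scaling (0.0523), library totals only (0.0519), a filter at a mean log2 CPM of 2 (0.0604) and limma-voom (0.0518). These 4 lists did not pass camera, with adjusted p of 0.479, 0.833, 0.487 and 0.831, though the FOXO list passed without wild-type replicate 3 (adjusted p 0.0426, and adjusted p 0.671 with an estimated correlation). The median and mean differed in sign for the FOXO (-0.01 and 0.06) and NF-kappaB lists (0.03 and -0.10). In 18 lists edgeR called 0 of 281 tested genes, against 26 at an unadjusted p under 0.05 and 5 in DESeq2. Beyond the lists above, these were the NSL complex (10 tested), YY1 and INO80 (14), other histone acetyltransferases and deacetylases (21, with 2 lower adjusted over the list alone), p53 targets (20), homologous recombination and Fanconi genes (27), glycolysis (21), the X inactivation centre (4), the mitochondrial genome (10) and the proteasome (37). None of those 9 passed camera, with adjusted p from 0.232 for glycolysis to 0.9 for the NSL complex, homologous recombination and the mitochondrial genome. Glycolysis passed without knockout replicate 1 (adjusted p 0.000245, and adjusted p 0.64 with an estimated correlation).

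**Figure D2:**
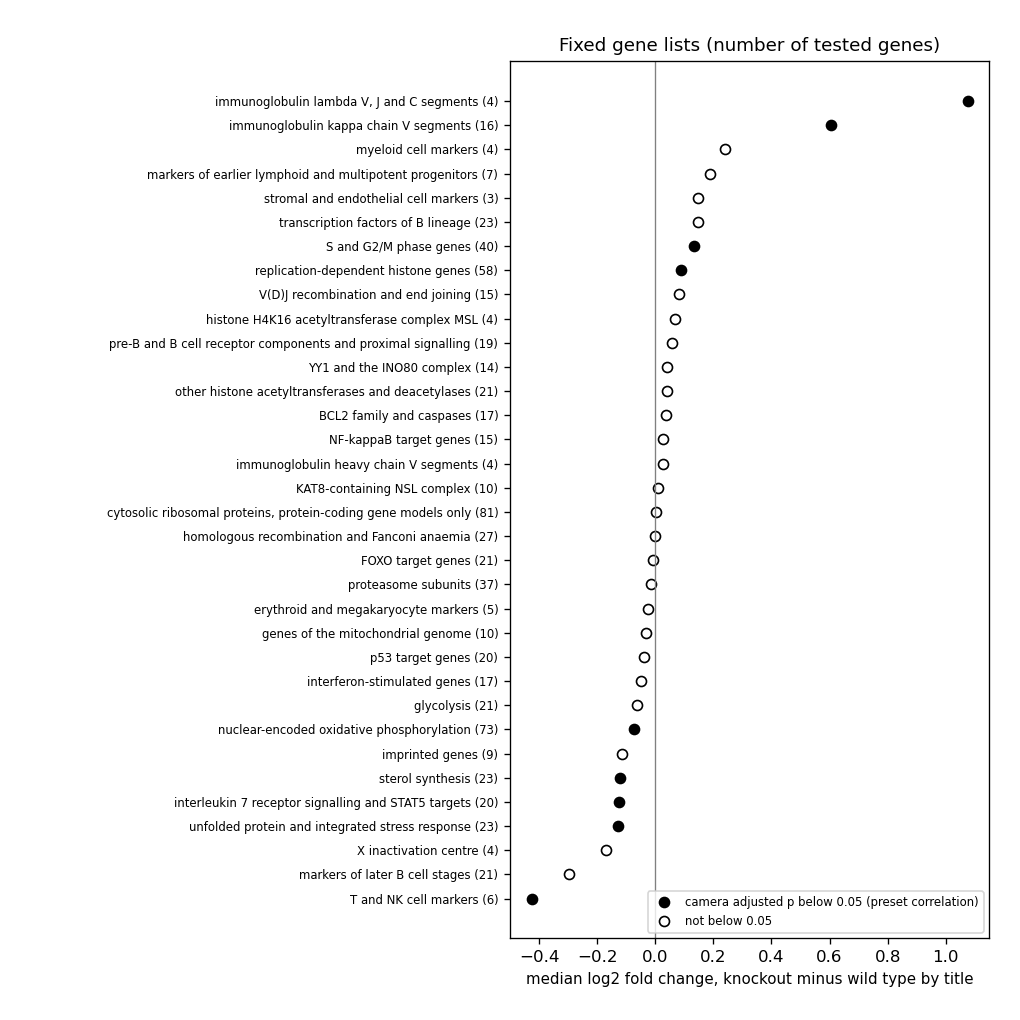
Median log2 fold change (horizontal axis, knockout minus wild type by title) of the 34 gene lists with at least 3 tested members, with the number of tested genes in brackets and 1 point per list. The 9 filled points passed camera with its preset correlation, and 0 lists passed with an estimated correlation, where 2 had an unadjusted p under 0.05.

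Since the MSL complex acts on the male X chromosome in flies, X-linked genes were compared with the rest. The 301 tested protein-coding X-linked genes had a median log2 fold change of 0.004, against -0.003 for 9994 autosomal genes, a difference of 0.0065 that ran from 0.0003 to 0.0201 without each library in turn. On the X, 12 genes rose and 10 fell, against 192 and 324 autosomal genes. Both directions together made up 7.31% and 5.16% of those tested (two-sided Fisher's exact p 0.113). Split by direction, a test chosen after the values were seen, the share that rose was 3.99% on the X and 1.92% on autosomes (Fisher's exact p 0.0189, or 0.0567 adjusted over the 3 such tests), and the share that fell 3.32% and 3.24% (p 0.869). For the share that rose, the unadjusted p was under 0.05 in 10 of 14 alternatives. Its smallest value was 0.000675 without the low-count filter, a fit that also tested genes passing the filter differently. Without wild-type replicates 1, 2 and 3 in turn the unadjusted p was 0.175, 0.0031 and 0.103, without knockout replicates 1, 2 and 3 in turn it was 0.436, 0.0575 and 0.0172, and without both libraries numbered 2 it was 8e-04. Genes are not independent replicates in these tests. Xist, the RNA that coats the inactive X, was at 382 ± 150 and 343 ± 94 CPM (adjusted p 0.881), and 0 of 8 Y-linked genes in the files passed the count filter. Of 20 chromosomes, camera called 0, with 0 at an unadjusted p under 0.05 and a smallest unadjusted p of 0.054 for chromosome 13. Without wild-type replicate 3, chromosome 13 passed (433 genes, median log2 fold change 0.06, adjusted p 0.00836, and adjusted p 0.567 with an estimated correlation).

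A run of 5 adjacent genes on chromosome 12 was lower in the knockout, chosen for mention after its values were seen. Adjacent here means among protein-coding genes with a known position and a mean log2 CPM of at least 2, without immunoglobulin segments. Other tested genes may lie between them. It spans 69189087 to 69357201 (mm10). Dnaaf2, an assembly factor of ciliary dynein, fell from 69.9 to 24.4 CPM on average (log2 -1.51 ± 0.13), Pole2, a subunit of DNA polymerase epsilon, from 318 to 161 CPM (log2 -0.98 ± 0.12) and Klhdc2, a substrate receptor of ubiquitin ligases, from 1257 to 570 CPM (log2 -1.14 ± 0.12). Klhdc1 (log2 -0.81 ± 0.13) and Nemf (log2 -0.35 ± 0.08) made up the rest, with adjusted p from 0.000205 for Dnaaf2 to 0.0261 for Nemf. The spans of Pole2 and Klhdc1 overlap, so reads there may be shared. On the side of Dnaaf2, the next genes of this kind were Mgat2 (log2 -0.41 ± 0.10, adjusted p 0.0503) and Rpl36al (-0.25, 0.453), followed by Lrr1 (-0.01, 0.988). On the side of Nemf, the next gene of this kind was Arf6 (-0.03, 0.94), and Map4k5, further on, was also lower (-0.62, 0.00514).

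**Figure D3:**
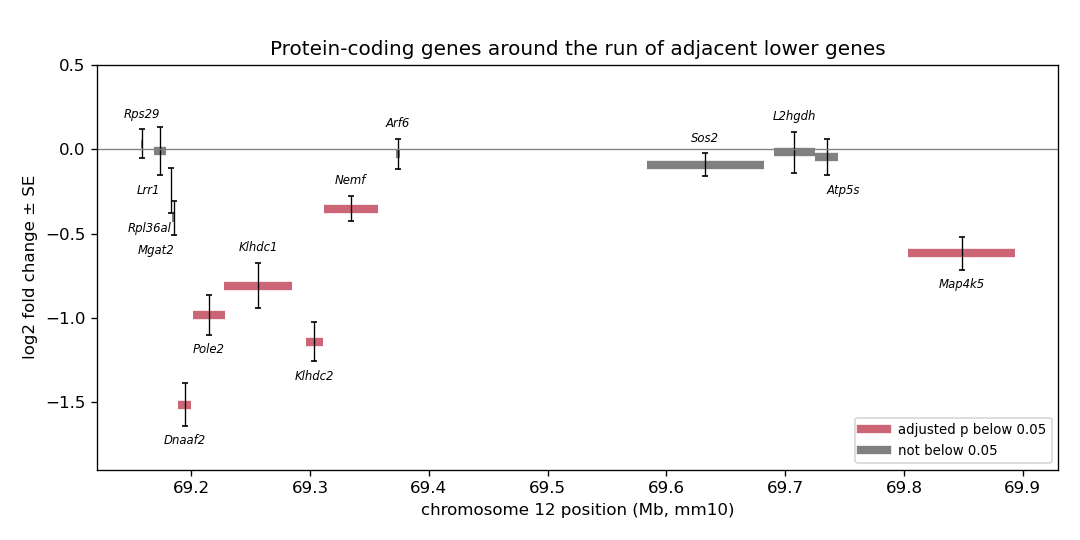
Log2 fold change ± SE (vertical axis) of protein-coding genes with a mean log2 CPM of at least 2 against their position on chromosome 12 in Mb (mm10), where each bar spans a gene and coloured bars mark an adjusted p under 0.05. The 5 adjacent genes from Dnaaf2 to Nemf lie between -1.51 and -0.35, Mgat2 beside Dnaaf2 lies at -0.41 without passing the threshold, and Arf6 beside Nemf lies at -0.03.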

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

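The alternative that left out both libraries numbered 2 was chosen after the data were seen, and the others before. Other scalings, DESeq2 and limma-voom kept the counts of called genes within 1.5 times of the reported ones, and DESeq2 called 766 genes, 579 of them among the 600. Without the low-count filter, 26696 genes were tested and the counts were 482 higher and 721 lower, with 185 and 312 at least 2-fold. With a mean log2 CPM of at least 2, fewer genes were tested (9635), and 231 were lower, 52 and 78 were at least 2-fold higher and lower, and 4 lists passed. The sterol and stress lists missed the threshold there, whereas the kappa V, lambda and T cell lists had under 3 tested members left and were not tested. Over the 6 fits that each left out 1 library, counts ranged from 138 to 227 higher and from 242 to 316 lower, lists from 5 to 10 and chromosomes from 0 to 1, with fewer samples in each fit. Without both libraries numbered 2, 224 genes were lower, and 344 of the 399 calls were among the 600. With an estimated correlation or with fry's directional test, 0 lists passed, against 2 and 6 at an unadjusted p under 0.05, and 0 lists passed with an estimated correlation in any alternative fit. The cause of that loss was not tested. Fry's mixed test, which asks whether genes of a list change in either direction and compares them with no other genes, passed 15 of 34 lists. Its smallest adjusted p were 1.92e-05 for B lineage factors, 0.000134 for T cell markers, 0.000352 for apoptosis genes, 0.000731 for imprinted genes and 0.000821 for kappa V segments.

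Replicate numbers were checked for pairing by the correlation of deviations from the group means between libraries of the same number. It was 0.03, 0.21 and 0.40 for numbers 1, 2 and 3. Wild-type replicate 1 and knockout replicate 2 correlated better with each other (0.27) than with their own numbers. Wild-type replicates 2 and 3 and knockout replicates 1 and 3 correlated best with their own number. The check therefore does not settle whether libraries of the same number were paired or shared a batch. With the number as a replicate block, 381 genes were higher and 565 lower, and 594 of the 600 calls were among these. The imprinted list passed camera with the block (adjusted p 0.022, and adjusted p 0.848 with an estimated correlation). Of 42 called genes named by the rule, 25 kept their call without each library in turn, 17 lost it at least once, and 12 lost it without both libraries numbered 2 (Atp5a1, Bcl2a1b, Bid, Ccnd3, Cenpe, Cenpf, Cited2, Cxcr4, Lat, Mcm5, Rpl22l1 and Spib). Of the 9 lists, 3 kept their call with the preset correlation without each library in turn (interleukin 7 signalling with STAT5 targets, kappa V and lambda segments), but in those fits their adjusted p with an estimated correlation ran from 0.326 to 0.933. None of the 600 called genes changed sign in an alternative that tested it, and no called list changed its camera direction, although the histone median was -0.033 without wild-type replicate 1. Msl2 ranged from 0.115 to 0.24 in log2 fold change without each library in turn, the X-linked difference from 0.0003 to 0.0201, and the genes near Msl2 from -0.023 to 0.219. Depth limits genes near the floor of 0.144 to 0.213 CPM per library.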

Other observations

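The tests and lists in this part were chosen after the results were seen, except the count over other splits of the libraries. Several genes of protein entry into and exit from the endoplasmic reticulum were lower in the knockout. A list was drawn up of the translocon, signal peptidase, oligosaccharyl transferase, coat complex, cargo receptors and degradation factors, and it also held Mzb1, which is of none of these classes. Of its 52 tested genes, 10 fell and 0 rose, or 19.2% against 2.73% of other genes (two-sided Fisher's exact p 1.41e-06). The genes that fell include Derl3 (27.9 ± 1.8 to 13 ± 3.1 CPM), Spcs2 (306 ± 11 to 202 ± 12 CPM), Mzb1 (49 ± 5.6 to 33.6 ± 1.3 CPM) and Lman1 (191 ± 14 to 152 ± 5.6 CPM). The list's median log2 fold change was -0.16, with a camera p of 5.33e-09 and a p of 0.124 with an estimated correlation. Bhlha15, a transcription factor of secretory cells, fell 3.86-fold, and Sdc1, a plasma cell surface marker, fell 2.15-fold.

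Several receptor genes for cytokines other than interleukin 7 were also lower. Of 33 tested receptor chains, 8 fell and 0 rose, or 24.2% against 2.74% of other genes (two-sided Fisher's exact p 2.57e-06). The list did not hold the cytokine receptor gene Flt3, which rose 2.71-fold, so the count of 0 depends on how the list was drawn. Examples besides Il7r were Il9r (2.19 ± 0.43 to 0.24 ± 0.096 CPM), Il4ra (30.1 ± 0.41 to 16.5 ± 2.3 CPM) and Csf2rb (144 ± 11 to 106 ± 4.4 CPM). The list's median log2 fold change was 0.06, opposite in sign to its called members, with a camera p of 0.0154 and a p of 0.338 with an estimated correlation. Since both lists were drawn up from the same values, and genes are not independent, their p-values are no independent evidence. Genes that rose outside the lists included Vim, an intermediate filament gene (160 ± 20 to 382 ± 63 CPM), the scavenger receptor genes Cd36 and Msr1 (2.09-fold and 2.93-fold), and Ccr2, with knockout replicates 1, 2 and 3 at 135, 54.8 and 31.7 CPM. Heavy chain V reads came almost wholly from 1 family in every library, Ighv14, which took between 98.3% and 99.9% of them in each.

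The 600 calls separate the groups as titled. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes, the real one, and the highest of the other splits called 0. With 10 splits no share under 0.05 can be reached. Zfp799 had 0 wild-type reads and 139 knockout reads, at least 42-fold higher over the group with a floor of 3 counts.

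The libraries numbered 2 held reads of some genes that were silent in their sister libraries. With at most 1 read in each of the other libraries of the group and at least 20 in replicates 1 and 3 of the other group, 6 genes were examined in wild-type replicate 2 and 13 in knockout replicate 2, of which 5 and 10 had over 3 reads there. If reads or cells of the other group had been mixed in, all such genes would appear at 1 common share of their level there. The shares ran from 0% for Zfp799 to 53.6% for Rag2 in wild-type replicate 2 and from 1.63% for Sox6 to 106% for Cenpb in knockout replicate 2. A chi-square test that allows a spread of 30% gave p of 6e-07 and 3.8e-23, which argues against such mixing as the whole cause in either library. Mixing as a part of the cause remains open. Between whole libraries, chi-square over degrees of freedom was 13.1 for the 2 libraries numbered 2. It was 10.9 and 16.6 for wild-type replicate 2 against wild-type replicates 1 and 3, and 15.5 and 7.29 for knockout replicate 2 against knockout replicates 1 and 3. By Spearman correlation each was nearer to its own group. Cultures made of subclones with different genes switched off may be another source, and no biological explanation was tested.

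The run of 5 adjacent lower genes on chromosome 12 was longer than gene order alone would often give. Among 10000 shuffled orders of the 8961 protein-coding genes with a mean log2 CPM of at least 2, 2 had a run as long (permutation p 3e-04). If RNA followed copy number alike in each gene, loss of 1 copy of the segment in the knockout line would lower all 5 by a like amount. Their log2 fold changes differed (heterogeneity p 4.88e-16), which argues against such a loss as the whole cause only under that condition. The SE used cover only the spread between libraries of 1 line per genotype. Reads shared among the 5 genes by overlap would leave the others alone, yet 3 of the called genes overlap no other gene of the run. Overlap with genes outside the run, such as antisense or non-coding genes, was not examined, so reads shared with those remain open. An effect of Msl2 loss on this segment and a difference that arose in 1 clone remain open, because each genotype is 1 line.

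Msl2 RNA was not lower in the knockout. Loss of the gene or its RNA in either group is argued against, since the size of the log2 fold change plus 2 SE was 0.352, below the 1 that a 2-fold change needs. Whether the titles or the genotype tags are right cannot be told apart from this gene. Its log2 fold change of 0.189 was not past the threshold in edgeR's test (adjusted p 0.302, unadjusted p 0.0434), and a small edit may leave RNA levels in place. If the tags are right, every direction given here is reversed.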
